A study of Mus musculus with 23 samples.

How the data were processed

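RNA of regulatory T cells (Treg) and CD8+ T cells was measured on mouse Illumina BeadChips, with 23 arrays in 8 groups of cell type, age (8 or 12 weeks) and genotype (NOD-LIRKO or NOD-Lox). Per the labels, total RNA was extracted with Trizol and labelled with biotin by the Encore Biotin IL protocol. The tissue of the cells, how they were isolated, the slide and the scan date of each array, and whether each array is a separate mouse are not given in the sources used here. The labels also mark each of the 12 NOD-LIRKO samples MIP and each NOD-Lox sample ctrl. What MIP stands for is not given in the sources used here, so whether these samples differ in more than the liver knockout is open. Replicate numbers follow the order of the samples and pair nothing.

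The deposited table of raw values holds 1 intensity per probe and array, not background corrected and not on a log scale, from 25.1 to 32773.1. The authors' processed values are log2 intensity, made by background correction, normalization between arrays and array quality weights in limma, and they run from 4.20 to 14.5 with array medians of 4.59 to 4.60. The raw intensity was used for all main results, and the authors' log2 values for 1 alternative. The values normalized here and the authors' had a correlation of 0.997. Raw medians per array were 44.6 to 75.5 and raw upper quartiles 61.9 to 173. The values used here hold no detection p.

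Intensities were background corrected by the normexp model of limma (saddle point method, offset 16), quantile normalized and put on the log2 scale. The deposited probes were 45281. The 25% with the lowest mean level were removed, which left 33960. The platform annotation gave 1 symbol for 34885 probes and several for 18, while 10378 probes on the array were not in it. Symbols were checked against the mouse gene reference, where 0 were updated and 78 were not found. For each gene the probe with the highest mean level was tested, and probes without a single gene name were tested as themselves, counted but not named. This gave 22850 features, of which 15067 carry a gene name and 7783 do not. Alb, a liver gene, was removed by the filter.

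A linear model with 1 mean per group and array weights (limma's arrayWeights) was fitted to all 23 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation. Contrasts were the genotype difference within each cell type and age, its mean over the ages, its change with age, its difference between cell types at each age, the age difference within each cell type and genotype, and Treg against CD8+ cells. P-values were adjusted by the method of Benjamini and Hochberg within each contrast, and a feature was called below 0.05.

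A set of 37 gene lists for T cell states, pathways, stress, and markers of other cell types was written before the data were examined, as were the contrasts, the rule for naming genes, the threshold and most alternatives. The lists hold 811 members, 70 of them without an annotated probe, and 683 were tested. They are Treg signature, CD8 identity, conventional CD4 markers, naive and central memory, cytotoxic effector, inhibitory receptors, T helper cytokines, T cell receptor early response, IL-2 and STAT5, TGF-beta, TNF and NF-kappaB, insulin, PI3K and mTOR, both interferon responses, chemokine receptors, apoptosis and type 1 diabetes susceptibility. The rest are cell cycle, glycolysis, oxidative phosphorylation, fatty acid oxidation, cholesterol and lipid synthesis, unfolded protein response, heat shock and handling stress, ribosomal proteins, complement and serpins, and markers of B, plasma, natural killer, dendritic, monocyte, neutrophil, erythroid, platelet, stromal, pancreatic and liver cells. Lists of at least 5 tested genes were tested with camera in limma at a preset correlation between genes of 0.01, and with an estimated correlation and with the directional test of fry as alternatives. The mixed test of fry, which counts changes in both directions, was reported after seeing the data and used for no call. Counts of genes in a list are given over all genes and adjusted over the list alone.

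Genes were named by a fixed rule. Where at least 5 passed in a direction, up to 8 with the largest difference and arrays that did not overlap were named, and otherwise the 5 with the smallest p in that direction. For a called list up to 4 members with the smallest p in its direction were named, and for a list described without a call up to 2. Insr, Alb, Serpinb1a, Foxp3, Il2ra, Ctla4, Cd8a, Cd8b1, Cd4, Gzmb, Ifng and Pdcd1 were always named in the genotype and age contrasts where tested. For changes of a difference the 5 genes with the smallest p were named. For the cell types, the 8 with the largest difference in each direction were named, with members of the Treg and CD8 lists.

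In 5 runs simulated with the same design and spread but uncorrelated genes, 200 differed and 1 list was shifted. At log2 differences of 1, 2 and 3, 53.9%, 91.6% and 99.4% were recovered in 8-week Treg, 45.2%, 88.4% and 98.8% in 12-week Treg, 0%, 7.16% and 33.7% in 8-week CD8+ cells and 22.7%, 73.7% and 89.6% in 12-week CD8+ cells. The means over both ages recovered 78.8%, 98.8% and 100% in Treg and 8.79%, 60.9% and 83.0% in CD8+ cells. A list shifted by 0.5 was called in 5, 5, 1 and 4 runs in those 4 contrasts, perhaps fewer if genes correlate.

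Alternatives changed 1 choice at a time, except that the intensity trend and robust variances were changed together. They were no array weights, no background correction, an offset of 50, median centring, the authors' values, no filter, all probes, an intensity trend with robust variances, each cell type alone, only the groups compared, an adjusted p below 0.10, an estimated correlation, fry, and each array left out in turn. Leaving out the 2 dim arrays, leaving out those and a Treg array that stands apart, the upper 50% of probes by mean level, the probe with the largest variance, and 1 surrogate variable from limma were chosen after seeing the data. Other splits of the arrays were counted for contrasts with at least 3 arrays per group, all 10 where there are 10 and otherwise 100 drawn with a fixed seed. No sample was left out of the main results.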

Results

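The arrays compare regulatory T cells (Treg) and CD8+ T cells of NOD-LIRKO mice, which lack the insulin receptor in the liver on the diabetes-prone NOD background, with those of NOD-Lox controls at 8 and 12 weeks of age. There are 3 arrays per group, except CD8+ cells of 8-week NOD-Lox mice with 2, so 23 arrays in all. The labels do not say that each array is a separate mouse, so the p-values below measure spread between these samples. Values are log2 intensity, given as mean ± SD of the arrays, and log2 differences are given with their standard errors (SE). The differences use array weights and the means do not, so the 2 need not match exactly and can differ in sign where the difference is small against its SE. A gene or list is called where its adjusted p is below 0.05, and each adjusted p comes from limma. The median level of all probes is 5.01, and a gene whose group mean is at or below it is at background in that group. The size of its difference is then uncertain, as is that of a change of a difference that includes such a group, and where both groups are at background no change can be read.

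Signal over background was uneven. The raw upper quartile was 1.55 to 2.62 times the raw median on 21 arrays, but 1.09 times on replicate 1 of the 8-week NOD-Lox CD8+ cells and 1.16 times on replicate 2 of the 12-week NOD-LIRKO CD8+ cells (the 2 dim arrays). Array weights, lower for noisier arrays, were 0.307 for that 12-week array and 0.803 to 2.66 for Treg. Both 8-week NOD-Lox CD8+ arrays had 0.124, so the dim replicate 1 counts as much as replicate 2. Mean correlation with the other arrays of the same cell type was 0.876 to 0.929 for Treg and 0.564 to 0.840 for CD8+ cells.

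**Figure D1:**
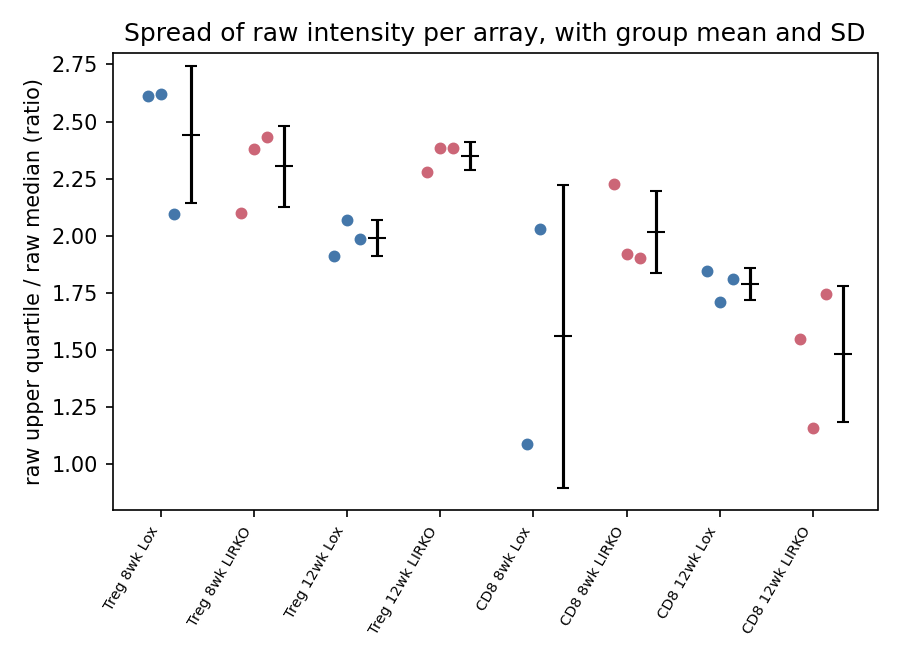
Raw upper quartile divided by raw median for each of the 23 arrays, with the mean and SD of each group. A low ratio means that few probes rise above the background of the array.

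Across all ages and genotypes (12 Treg arrays against 11 CD8+ arrays), Ctla4, an inhibitory receptor of Treg, was at 9.62 ± 0.29 in Treg and 5.77 ± 0.59 in CD8+ cells (log2 difference 3.85, SE 0.26, adjusted p = 1.42e-07). Klrd1, a receptor of natural killer and CD8+ T cells, was at 6.31 ± 0.54 and 9.79 ± 0.22 (−3.58, SE 0.32, adjusted p = 3.37e-06). The other large differences toward Treg were Ccr6, a chemokine receptor (4.22), Nrn1 (3.91), Tiam1 (3.84), Capg (3.78), Tnfrsf4, a costimulatory receptor (3.71), Nrp1 (3.63) and Gm5796 (3.53). Those toward CD8+ cells were Dapl1 (−3.37), the Ly49 receptor genes Klra7 (−3.15), Klra16 (−3.12) and Klra22 (−3.11), then Tmem108 (−2.91), Trnp1 (−2.90) and Lcn4 (−2.86). Klra7, Tmem108 and Trnp1 are at background in Treg. Arrays of the 2 cell types overlapped for Nrn1, Klra7 and Trnp1, and not for the others named here. In all, 758 of 22850 features were called, 470 higher and 288 lower in Treg, of which 565 carry a gene name, and 4376 had an unadjusted p under 0.05.

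The Treg signature list was higher in 23 of its 24 measured genes (median 2.35, adjusted p = 1.07e-40, or adjusted p = 0.000296 with an estimated correlation). Of these, 19 were called over all genes and all 19 were higher, with Cd4 (3.52), Izumo1r, the folate receptor 4 (2.65), and Fgl2 (1.79) among them. Adjusted over the list alone, 23 were higher and 1 lower. The CD8 identity list was lower in 11 of 12 (median −1.23, adjusted p = 6.72e-10, or 0.00193 with an estimated correlation), with 7 called lower and 1 higher over all genes, and 9 lower and 1 higher adjusted over the list alone. Gzmm (−1.90) and Nkg7 (−1.57) of the cytotoxic granule and the chemokine Ccl5 (−1.44) were among its called genes. Some chosen probes separated the cells poorly, as the most abundant probe of a gene need not be its most specific. The chosen Foxp3 probe was at 10.02 in Treg and 8.69 in CD8+ cells, that of Cd8b1 at 8.92 and 8.02, and that of Cd8a at 6.40 and 6.96. Other probes, chosen after their values were seen, separated them better. The other 3 Foxp3 probes were at 8.37, 10.24 and 9.05 in Treg and 4.95, 6.26 and 5.22 in CD8+ cells, a second Cd8b1 probe at 5.26 ± 0.33 and 10.36 ± 0.24, and a second Cd8a probe at 4.62 and 8.65.

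Beyond identity, several other lists were higher in Treg. The cell cycle list was higher in 31 of 32 genes (median 0.90, adjusted p = 1.79e-15, or 0.00281 with an estimated correlation). Over all genes 8 were called, among them Rrm2 of nucleotide synthesis (1.81) and the kinase Plk1 (2.44), and 21 higher and 1 lower adjusted over the list alone. In the same direction went conventional CD4 T cell markers (9 of 9 higher, median 0.99, adjusted p = 6.76e-14) and T helper cytokines and regulators (14 of 15, 1.19, adjusted p = 8.77e-13). So did IL-2 and STAT5 signalling (19 of 24, 0.87, adjusted p = 7.41e-12) and inhibitory receptors (15 of 18, 0.72, adjusted p = 8.12e-12). Over all genes 5, 7, 8 and 5 of these were called, all higher, and 8, 10, 10 and 12 adjusted over the list alone. Smaller shifts toward Treg were called for interferon gamma response (23 of 28 higher, median 0.37, adjusted p = 2.32e-07), glycolysis (16 of 18, 0.35, adjusted p = 7.20e-06), unfolded protein response (21 of 25, 0.23, adjusted p = 5.92e-05) and TNF and NF-kappaB signalling (17 of 20, 0.51, adjusted p = 6.72e-05). Plasma cell markers (7 of 8, 0.56, adjusted p = 0.000229), T cell receptor early response (14 of 24, 0.19, adjusted p = 0.000510), chemokine receptors (14 of 21, 0.40, adjusted p = 0.000555) and type 1 diabetes susceptibility genes (18 of 29, 0.16, adjusted p = 0.000752) were called too. So were apoptosis (16 of 20, 0.28, adjusted p = 0.00119), oxidative phosphorylation (23 of 34, 0.09, adjusted p = 0.000896, but 0.0714 with an estimated correlation) and monocyte and macrophage markers (12 of 18, 0.23, adjusted p = 0.0346, but 0.276 with an estimated correlation). In the order given, these 11 lists held 3, 1, 2, 4, 3, 4, 7, 4, 0, 3 and 0 genes called over all genes, all higher except 1 of TNF and 2 of chemokine receptors. Adjusted over the list alone the counts were 11, 4, 4, 7, 3, 6, 12, 10, 0, 3 and 0, of which 1 interferon, 2 TNF, 4 chemokine receptor and 2 susceptibility genes were lower. The monocyte call was lost in 16 of 38 alternatives (adjusted p from 0.00101 to 0.276). Single arrays whose loss ends it are CD8+ 8-week NOD-Lox replicate 2 (0.176), CD8+ 12-week NOD-Lox replicate 2 (0.0529) and NOD-LIRKO replicate 3 (0.0559). So are Treg 8-week NOD-Lox replicate 1 (0.0565) and NOD-LIRKO replicates 2 (0.0506) and 3 (0.0592), and Treg 12-week NOD-Lox replicate 1 (0.0509) and NOD-LIRKO replicates 1 (0.0583) and 2 (0.0717).

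Toward CD8+ cells went natural killer cell markers (10 of 12 lower, median −0.81, adjusted p = 8.13e-05) and the naive and central memory list (12 of 16 lower, −0.27, adjusted p = 0.000676), which includes Ccr7, the lymph node homing receptor (−0.94), and Lef1 (−0.64). Over all genes 4 and 5 of these were called, all lower, and adjusted over the list alone 6 and 6 lower and 1 naive gene higher. The naive list lost its call in 1 of 38 alternatives, without replicate 2 of 8-week NOD-Lox CD8+ cells (adjusted p = 0.111, range 1.40e-05 to 0.111). The lists share members, as 13 of 24 Treg signature genes, 7 of 12 CD8 identity genes and 5 of 12 natural killer genes stand in another list too. The cytotoxic effector list was not called (13 genes higher, 13 lower, adjusted p = 0.214), though over all genes 3 of its members were called higher and 6 lower, and adjusted over the list alone 7 and 13. The other lists, not called, were hepatocyte, erythroid, dendritic, pancreatic, platelet, B cell, stromal and neutrophil markers, cholesterol, type I interferon, fatty acid oxidation, complement and serpins, TGF-beta, heat shock, ribosomal proteins and insulin signalling (adjusted p from 0.0621 to 0.570). Without replicate 1 or 2 of the 8-week NOD-Lox CD8+ cells the gene count was 2257 or 8591 in place of 758. With each array centred on its median in place of quantile normalization, 1153 of the called genes were higher and 245 lower (82.5% higher, against 62.0% with 470 and 288), so the balance of directions rests on the scaling.

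In Treg of 8-week mice, heat shock and handling stress genes were higher in NOD-LIRKO than in NOD-Lox (n = 3 each). The list was higher in 13 of 17 genes (median 0.44, adjusted p = 0.000876), but the call is lost where the correlation between genes is estimated (adjusted p = 0.454 with an estimated correlation). Examples are the chaperones Hsp90aa1 (11.57 ± 0.23 against 10.89 ± 0.04, difference 0.75, SE 0.20), Hsph1 (0.93, SE 0.25), Hspe1 (0.55, SE 0.15) and Hspa1b (1.09, SE 0.43). None of the 17 was called over all genes, 3 were called higher adjusted over the list alone (Hsp90aa1, Hsph1 and Hspe1, each adjusted p = 0.00945), and 7 had an unadjusted p under 0.05. The list median per array, relative to the mean of all Treg arrays, was 0.13, 0.02 and 0.38 in NOD-LIRKO and −0.14, −0.25 and −0.14 in NOD-Lox, so all 3 lay above all 3.

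No single gene was called in 8-week Treg (limma, smallest adjusted p = 0.107, 1441 features at an unadjusted p under 0.05). The smallest p-values toward higher levels were those of Ak7, an adenylate kinase (6.18 ± 0.32 against 5.23 ± 0.43, difference 0.99, SE 0.17, adjusted p = 0.107) and Slc25a26, a mitochondrial carrier (1.39, SE 0.26, adjusted p = 0.164). Then came Stk19 (1.09, SE 0.22), Slc6a6, the taurine transporter (0.60, SE 0.13), and Slc29a3 (0.60, SE 0.13). Toward lower levels they were Myo3b (4.85 ± 0.11 against 6.07 ± 0.44, −1.26, SE 0.20, adjusted p = 0.107), Prdx4, a peroxiredoxin of the endoplasmic reticulum (−0.96, SE 0.18, adjusted p = 0.164), followed by Gstp3 (−1.15, SE 0.24), Nr2c2ap (−1.49, SE 0.32) and Ganc (−2.0, SE 0.44). All 10 had arrays not overlapping by genotype. Chance gives this for 10% of all genes, and picking by p favours it. Slc25a26 and Serpinb1a are at background in NOD-Lox and Myo3b in NOD-LIRKO. Foxp3, the lineage factor of Treg, differed by 0.23, Il2ra by −0.07, Ctla4 by 0.17, Pdcd1 by −0.27, Insr by −0.46 (SE 0.60, adjusted p = 0.985) and the serpin gene Serpinb1a by 0.07. Cd4 (0.06), Cd8a (0.51), Cd8b1 (−0.19), Gzmb (0.07) and Ifng (0.07) were not called either. On the second probes named above Cd8a differed by 0.01 and Cd8b1 by −0.13, and the other 3 Foxp3 probes by −0.10, −0.02 and 0.05. Since the receptor was deleted in liver, Insr in T cells checks nothing about the knockout. Next after heat shock came interferon gamma response, cholesterol and lipid synthesis, erythroid markers and type 1 diabetes susceptibility genes (each adjusted p = 0.0735), with cholesterol genes lower in 13 of 16 and its gene Cyp51, the lanosterol demethylase, at −0.78. Fry called the cholesterol list (adjusted p = 0.0128) and not heat shock (adjusted p = 0.282), while an estimated correlation called neither (0.410 and 0.454). Leaving out 1 array gave up to 6 genes (without NOD-LIRKO replicate 3) or 5 (without NOD-Lox replicate 3) and 1 or 2 without 8 further arrays named in the closing part. The simulation at this design recovered 53.9% of genes set to differ by log2 1.

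**Figure D2:**
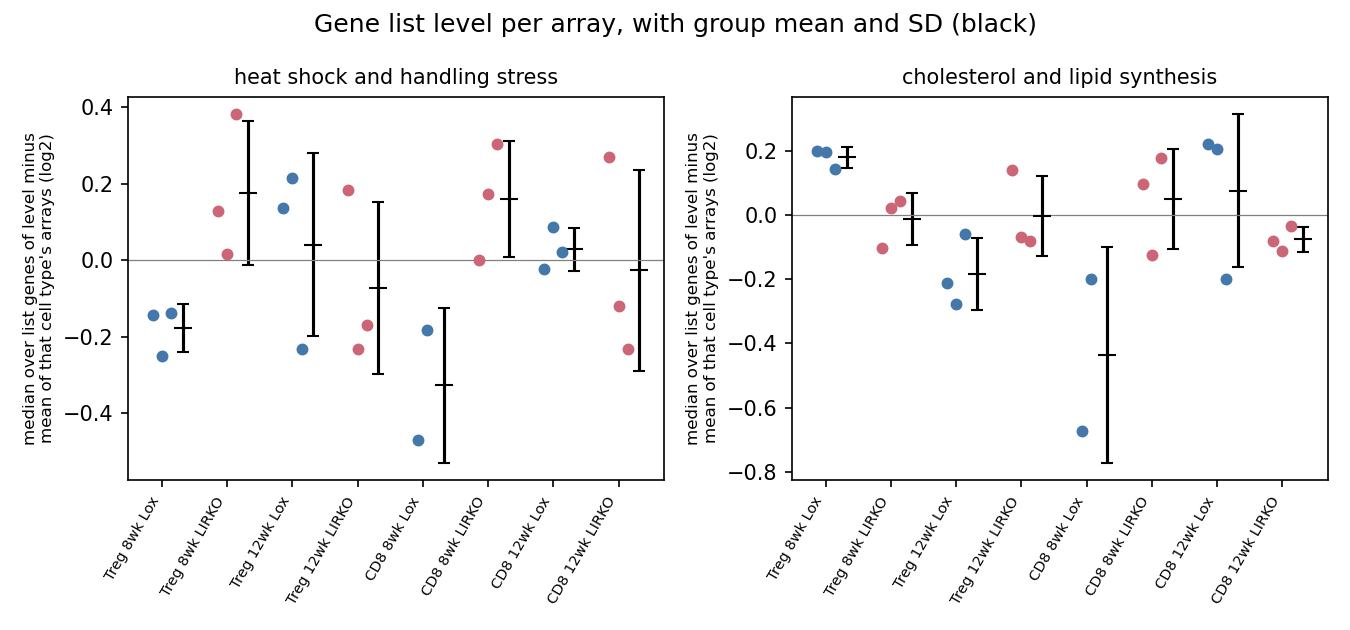
Median level per array of the heat shock and handling stress list and of the cholesterol and lipid synthesis list, relative to the mean of the arrays of the same cell type. Each point is 1 array, and bars are the mean and SD of each group.

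In Treg of 12-week mice, Dok4, an adaptor of the docking protein family downstream of receptor tyrosine kinases, was lower in NOD-LIRKO. Its level was 5.45 ± 0.26 against 7.80 ± 0.46 in NOD-Lox (n = 3 each, difference −2.33, SE 0.27, 5.02-fold lower, adjusted p = 0.00256), and all 3 NOD-LIRKO arrays lay below all 3 NOD-Lox arrays. It is the 1 gene called of 22850, on the single probe of the gene (ILMN_1241168), and 1726 features had an unadjusted p under 0.05. The call was kept in 37 of 39 alternatives (adjusted p from 9.21e-05 to 0.524) and lost with each cell type fitted alone (adjusted p = 0.200) or with only the 2 groups compared in the fit (adjusted p = 0.524).

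The other genes with the smallest p-values in 12-week Treg were not called. Toward higher levels they were Adam10, a cell surface metalloprotease (0.71, SE 0.14, adjusted p = 0.213), Cyp51 (6.50 ± 0.24 against 5.23 ± 0.04, 1.28, SE 0.26, adjusted p = 0.223), Tnrc18 (1.44, SE 0.31), Phf1 (1.49, SE 0.32) and Eef1aknmt (1.51, SE 0.34). Toward lower levels, after Dok4, they were Wdr59 (−1.70, SE 0.30, adjusted p = 0.177), Gja1, the gap junction protein connexin 43 (−2.06, SE 0.39, adjusted p = 0.183), Krt90 (−0.87, SE 0.18) and Tmem97 (−1.30, SE 0.28, adjusted p = 0.240). Gja1 is at background in NOD-LIRKO and Serpinb1a in NOD-Lox. Foxp3 was at 9.57 ± 1.37 against 10.16 ± 0.32 (−0.33, SE 0.48, or 0.27 without NOD-LIRKO replicate 3) and Insr at 6.36 ± 0.33 against 6.17 ± 1.93, where the weighted difference (−0.24, SE 0.68) has the opposite sign to that of the plain means. Serpinb1a differed by 0.62 (SE 0.23, adjusted p = 0.552), Cd4 by 0.45, Ifng by 0.39, Gzmb by 0.30, Ctla4 by 0.18, Cd8a by −0.02, Pdcd1 by −0.06, Cd8b1 by −0.33 and Il2ra by −0.42. The second probes of Cd8a and Cd8b1 differed by 0.10 and 0.13, and the other 3 Foxp3 probes by −0.37, −1.08 (SE 0.52, adjusted p = 0.708) and −0.21. None of the 37 lists was called or had an unadjusted p under 0.05 (camera in limma, smallest adjusted p = 0.870). NOD-LIRKO replicate 3 stood apart here, with Treg signature genes at a median of −0.99 against the other Treg arrays, which ranged from −0.09 to 0.33. Without NOD-LIRKO replicate 1, 2 or 3 the gene count was 2, 3 or 6, and without NOD-Lox replicate 1, 2 or 3 it was 5, 6 or 6. It was 2 without 8-week NOD-LIRKO Treg replicate 3, 8-week NOD-LIRKO CD8+ replicate 1 or 12-week NOD-Lox CD8+ replicate 1.

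Averaged over both ages, Dok4 was the gene called in Treg, at 5.53 ± 0.40 in NOD-LIRKO and 6.98 ± 0.95 in NOD-Lox (n = 6 each, difference −1.38, SE 0.18, adjusted p = 0.0140). The arrays of the genotypes overlapped at 1 of the ages, and the change of the difference with age was not called (−1.90, SE 0.37, adjusted p = 0.247). The next genes were Tnrc18 (1.18, SE 0.21), Slc6a6 (0.54, SE 0.10) and Dnm2, the dynamin of endocytosis (1.21, SE 0.22), each with an adjusted p = 0.156, then Slc26a11 (1.07, SE 0.20) and Ago2 of the microRNA pathway (0.43, SE 0.09). Lower but not called were Larp4 (−0.66, SE 0.13, adjusted p = 0.170), Prdx4 (−0.68, SE 0.13, adjusted p = 0.182), Tex2 (−0.67, SE 0.14) and Ints1 (−0.80, SE 0.18). No list was called (camera in limma, smallest adjusted p = 0.398, 2 lists and 1702 features at an unadjusted p under 0.05), and fry called conventional CD4 T cell markers (higher, adjusted p = 0.0382, against 0.398 with camera). Serpinb1a differed by 0.34, Cd4 by 0.26, Cd8a by 0.25, Ifng by 0.23, Gzmb by 0.19, Ctla4 by 0.17, Foxp3 by −0.05, Pdcd1 by −0.16, Il2ra by −0.24, Cd8b1 by −0.26 and Insr by −0.35, none of them called. The second probes of Cd8a and Cd8b1 differed by 0.05 and 0.001, and the other 3 Foxp3 probes by −0.24, −0.55 and −0.08. Serpinb1a is at background in NOD-Lox. The Dok4 call was lost in 6 of 39 alternatives (adjusted p from 0.000285 to 0.408), among them leaving out replicate 1 (0.103) or replicate 2 (0.0552) of 8-week NOD-Lox and leaving out the 2 dim arrays (0.0667).

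**Figure D3:**
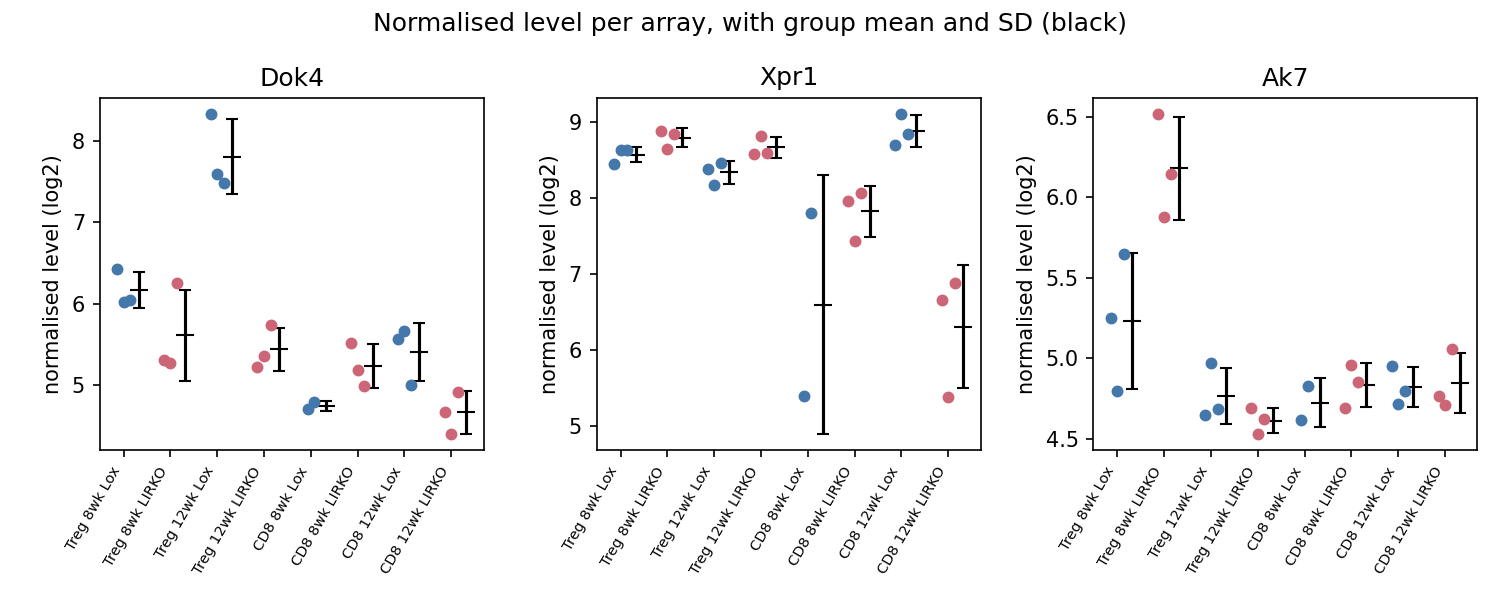
Levels of Dok4, Xpr1 and Ak7 on each array, with the mean and SD of each group. Levels are log2 intensity after normalization.

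In CD8+ cells of 8-week mice, no gene and no list was called (limma, smallest adjusted p = 0.778 for genes and 0.0903 for lists, with 1445 features and 9 lists at an unadjusted p under 0.05). This rests on the choices made, as 672 genes were called without array weights and 15 lists with median centring, where the median of all features was 0.20. The smallest p-values toward higher levels in NOD-LIRKO (n = 3 against 2) belonged to Atpif1, the inhibitor of the mitochondrial ATP synthase (10.35 ± 0.18 against 7.25 ± 2.98, difference 3.10, SE 0.66). Next were Csnk1a1 (2.48, SE 0.61), Pon2 (3.18, SE 0.79), Wsb1 (2.86, SE 0.71) and Traf6, a ubiquitin ligase of inflammatory signalling (2.84, SE 0.71). Toward lower levels they were Cpe, a carboxypeptidase of hormone processing (4.78 ± 0.23 against 7.08 ± 0.22, −2.29, SE 0.50), Fbxo40 (4.85 ± 0.15 against 7.46 ± 0.05, −2.61, SE 0.63), Dppa5a (−1.63, SE 0.40), Hrh2 (−1.70, SE 0.44) and Vmn1r45 (−1.75, SE 0.47). Each of the 10 had an adjusted p = 0.778. In NOD-LIRKO, Cpe, Fbxo40, Dppa5a, Vmn1r45, Serpinb1a, Gzmb and Ifng are at background, in NOD-Lox Pdcd1, and in both Il2ra. The nearest lists were unfolded protein response (median 0.48, with Hsp90b1 at 1.16 and Ddit3 at 2.15), hepatocyte markers (−0.61), interferon gamma response (0.22) and oxidative phosphorylation (0.27), each with an adjusted p = 0.0903. Gzmb differed by −0.41, Ifng by −0.37, Pdcd1 by 0.32, Serpinb1a by −1.04, Insr by 0.79 (SE 2.01), Cd8a by −0.25, Cd8b1 by −0.24, Cd4 by −0.30, Foxp3 by 0.17, Il2ra by −0.11 and Ctla4 by 0.53. The second probe of Cd8a differed by −0.30 and that of Cd8b1 by 0.11. The 2 NOD-Lox arrays carry equal low weights, and the count rose without either, which leaves 1 array whose spread is taken from the other groups. The simulation recovered 0% of genes set to differ by log2 1 and 33.7% of those set to differ by 3, so a lack of calls here says little.

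In CD8+ cells of 12-week mice, Xpr1, the phosphate exporter that also serves as a receptor of xenotropic and polytropic retroviruses, was lower in NOD-LIRKO. Its level was 6.31 ± 0.81 against 8.88 ± 0.21 (n = 3 each, difference −2.33, SE 0.29, 5.03-fold lower, adjusted p = 0.00675), lower in 3 of 3 arrays. It is the 1 gene called, and the call rests on 1 of its 7 probes (ILMN_1214765). The other 6 probes had differences from −0.34 to 0.20 and limma p-values from 0.45 to 0.90. The call was kept in 37 of 39 alternatives (adjusted p from 0.00108 to 0.375) and lost with each cell type fitted alone (0.344) or with only the groups compared (0.375).

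Genes near the threshold in 12-week CD8+ cells included Hnrnpll, a splicing regulator of T cell activation (9.16 ± 0.24 against 7.54 ± 0.18, 1.71, SE 0.30, adjusted p = 0.132) and the kinase Mark3 (1.79, SE 0.33, adjusted p = 0.132). Then came Creb3, a transcription factor bound to the endoplasmic reticulum (9.42 ± 0.53 against 6.65 ± 0.15, 2.65, SE 0.50, adjusted p = 0.136), Pla2g3 (1.91, SE 0.32, adjusted p = 0.132, arrays overlapping) and Prdx4 (1.36, SE 0.27, adjusted p = 0.184). Toward lower levels were Tmem141 (−1.27, SE 0.22), Rnf169 (−1.42, SE 0.26), Armt1 (−1.54, SE 0.29) and Alg1 (−1.69, SE 0.32), each with an adjusted p = 0.132. Alg1 is at background in NOD-LIRKO. Pla2g3, Prdx4, Gzmb, Ifng, Serpinb1a and Il2ra are so in NOD-Lox, and Pdcd1 in both. Gzmb, the effector protease granzyme B, was at 5.57 ± 0.83 against 4.51 ± 0.37 (1.31, SE 0.30, adjusted p = 0.218), with overlapping arrays. Cd4 differed by 0.95 (SE 0.37, adjusted p = 0.568), Serpinb1a by 0.85 (SE 0.31, adjusted p = 0.522), Ifng by 0.65, Insr by 0.36, Il2ra by 0.34, Cd8a by −0.02, Pdcd1 by −0.19, Ctla4 by −0.25, Foxp3 by −0.27 and Cd8b1 by −0.44. The second Cd8a probe was higher (0.51, SE 0.22, adjusted p = 0.634, unadjusted p under 0.05) and the second Cd8b1 probe lower (−0.38). No list was called (camera in limma, smallest adjusted p = 0.175, 5 lists and 1690 features at an unadjusted p under 0.05). Interferon gamma response (22 of 28 lower, median −0.21) and cell cycle (24 of 32 higher, 0.25) had that p. The cytotoxic effector list was higher in 19 of 26 (0.43, adjusted p = 0.298), with Gzmb the 1 gene called adjusted over the list alone. Without NOD-LIRKO replicate 1, 2 or 3 the gene count was 3, 4 or 2, and without NOD-Lox replicate 2 or 3 it was 4 or 2. It was 2 also without 8-week NOD-LIRKO CD8+ replicate 2 or 3 or 8-week NOD-Lox Treg replicate 1.

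Averaged over both ages, CD8+ cells showed no called gene or list between genotypes (limma, smallest adjusted p = 0.975 for genes and 0.221 for lists, with 1149 features and 7 lists at an unadjusted p under 0.05, where chance gives 1142.5 features). The smallest p-values (n = 6 against 5, each adjusted p = 0.975) were those of Reck, a membrane inhibitor of metalloproteases (1.68, SE 0.33), Atpif1 (1.61), Arl1 (1.84), Wsb1 (1.60) and Stag1 of the cohesin complex (1.58). Toward lower levels were Scand1 (−1.49, SE 0.36), Cpe (−1.14), Acer1 (−0.82), Fbxo40 (−1.40) and Dppa5a (−0.82). Dppa5a is at background in NOD-LIRKO, Gzmb and Ifng in NOD-Lox, and Il2ra and Pdcd1 in both. Insr differed by 0.58, Gzmb by 0.45, Cd4 by 0.32, Ctla4 by 0.14, Ifng by 0.14, Il2ra by 0.12, Pdcd1 by 0.07, Foxp3 by −0.05, Serpinb1a by −0.09, Cd8a by −0.13 and Cd8b1 by −0.34 (second probes 0.10 and −0.13). The count was 93 without replicate 1 of 8-week NOD-Lox and 6803 without replicate 2. In no genotype comparison within a cell type was the insulin, PI3K and mTOR list called with camera or with the directional test of fry. Its adjusted p with camera was 0.971 and 0.870 in Treg and 0.323 and 0.784 in CD8+ cells at 8 and 12 weeks, and the Treg signature, cytotoxic effector and complement and serpin lists were not called by these 2 tests either. The mixed test of fry, which counts changes in both directions, did call insulin signalling and cytotoxic effector in 12-week CD8+ cells (each adjusted p = 0.00586). They were among 6 lists it called there, with 0 to 2 in the other genotype contrasts within a cell type. Adjusted over the list alone, 1 cytotoxic gene in 12-week CD8+ cells and 1 complement and serpin gene in 12-week Treg were higher, and 1 Treg signature gene was lower over both ages in Treg.

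The genotype difference of heat shock genes in Treg changed with age. The difference NOD-LIRKO minus NOD-Lox was lower at 12 than at 8 weeks in 15 of 17 genes (median −0.47, adjusted p = 0.000544, but adjusted p = 0.751 with an estimated correlation). The members with the smallest p were Fos (−1.62), Dnajb4 (−1.28), Hsph1 (−1.09) and Hsp90aa1 (−0.69). That of the cholesterol and lipid synthesis list went the other way, higher at 12 weeks in 12 of 16 (median 0.32, adjusted p = 0.0425, but 0.191 with an estimated correlation), with Cyp51 (2.06), Lss (1.32), Msmo1 (0.91) and Scd2 (0.85) of sterol and fatty acid synthesis. None of the 17 heat shock genes and 1 of the 16 cholesterol genes, Cyp51 (adjusted p = 0.000235), changed with age adjusted over the list alone. No gene was called over all genes (limma, smallest adjusted p = 0.105, 1447 features at an unadjusted p under 0.05). The smallest p-values were those of Cyp51 (SE 0.35, adjusted p = 0.105), Stk19 (−1.96, SE 0.34, adjusted p = 0.105), Sdhb (1.33, SE 0.24, adjusted p = 0.143), Dok4 (−1.90, adjusted p = 0.247) and Stk32a (−1.45, SE 0.30, adjusted p = 0.349). The heat shock call was lost in 3 of 41 alternatives (adjusted p from 8.39e-08 to 0.751), among them without 12-week NOD-Lox replicate 2 (0.0505). The cholesterol call was lost in 13 of 41 (0.00273 to 0.191), without replicate 2 of 12-week NOD-Lox at 0.162, and without 7 other arrays at 0.0511 to 0.0852. These are Treg 8-week NOD-Lox replicates 1 (0.0562) and 2 (0.0546), Treg 8-week NOD-LIRKO replicate 2 (0.0852), Treg 12-week NOD-Lox replicate 3 (0.0830), Treg 12-week NOD-LIRKO replicate 1 (0.0778), CD8+ 8-week NOD-Lox replicate 2 (0.0511) and CD8+ 12-week NOD-Lox replicate 3 (0.0624).

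In CD8+ cells the test of age by genotype called 3 lists. The genotype difference (NOD-LIRKO minus NOD-Lox) of interferon gamma response genes was lower at 12 than at 8 weeks in 22 of 28 (median −0.51, adjusted p = 0.0237), with the guanylate binding proteins Gbp2 (−2.08) and Gbp3 (−1.87), Tap1 of antigen processing (−1.96) and Irgm2 (−1.43). That of oxidative phosphorylation genes was lower in 26 of 34 (−0.25, adjusted p = 0.0340), with Sdha (−2.44), Atp5j (−1.03), Cox5a (−0.93) and Atp5c1 (−0.81). That of hepatocyte markers was higher in 7 of 9 (0.46, adjusted p = 0.0408), with the liver secretory protein genes Ahsg (2.0), Ttr (1.25), Serpina1c (1.18) and Serpina1a (1.05). All 3 calls are lost with an estimated correlation (adjusted p = 0.558 for each) and no member was called over all genes or adjusted over the list alone. Without replicate 1 of 8-week NOD-Lox the 3 adjusted p-values were 0.914, 0.117 and 0.914, over ranges of 2.08e-05 to 0.964, 2.92e-08 to 0.561 and 0.00613 to 0.964 across the alternatives. The oxidative phosphorylation call was also lost without 8-week replicate 2 of NOD-Lox (0.105) or of NOD-LIRKO (0.0720) and 12-week NOD-Lox replicate 3 (0.0750). The hepatocyte call was lost without 10 arrays in all. The other 9 are CD8+ 8-week NOD-Lox replicate 2 (0.0611) and NOD-LIRKO replicates 1 (0.0589) and 3 (0.0595), CD8+ 12-week NOD-Lox replicates 2 (0.0803) and 3 (0.0750) and NOD-LIRKO replicate 1 (0.0853). The last 3 are Treg 8-week NOD-LIRKO replicate 2 (0.0506), 12-week NOD-Lox replicate 3 (0.0522) and 12-week NOD-LIRKO replicate 1 (0.0509). No gene was called (limma, 1655 features at an unadjusted p under 0.05), and Xpr1 (−3.53, SE 0.72), Hrh2 (2.13), Cpe (2.29), Podnl1 (−2.59) and Atpif1 (−2.98) had the smallest p-values, each with an adjusted p = 0.660. The gene count was 51 without that array and 7451 without replicate 2.

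Between cell types, the genotype difference of Xpr1 at 12 weeks differed between CD8+ cells and Treg (Treg minus CD8+ 2.71, SE 0.37, adjusted p = 0.0179), the 1 gene called, with 1699 features at an unadjusted p under 0.05. The call was lost in 8 of 38 alternatives (adjusted p from 0.00256 to 0.294), among them without array weights (0.294) and without each of 6 arrays. These are Treg NOD-Lox replicate 1, 2 or 3 (0.0690, 0.0842, 0.0620), Treg NOD-LIRKO replicate 2 (0.0786), CD8+ NOD-Lox replicate 3 (0.0942) and CD8+ NOD-LIRKO replicate 1 (0.0646). Prdx4 (−1.75), Creb3 (−3.17), Mark3 (−2.09) and Ifi30 (2.12) had an adjusted p = 0.251 each, and no list was called (camera in limma, smallest adjusted p = 0.228, 3 lists at an unadjusted p under 0.05). At 8 weeks no gene was called (limma, 1578 features at an unadjusted p under 0.05), with Atpif1 (−3.13, SE 0.68), Fbxo40 (2.94), Cpe (2.28), Nr2c2ap (−4.84) and Sgpp1 (−3.17) at an adjusted p = 0.701. Interferon gamma response was the 1 list called there, its genotype difference lower in Treg than in CD8+ cells in 21 of 28 genes (median −0.26, adjusted p = 0.0460, but 0.406 with an estimated correlation), with Gbp3 (−2.09), Cd274, which encodes PD-L1 (−2.07), Gbp2 (−2.0) and Irf1 (−1.09). That call was lost in 22 of 40 alternatives (3.42e-05 to 0.860), without replicate 1 of 8-week NOD-Lox CD8+ cells at 0.80 and without 12 arrays in all at 0.0501 to 0.80.

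With age, Ak7 fell in Treg of NOD-LIRKO mice. Its level was 6.18 ± 0.32 at 8 weeks and 4.61 ± 0.08 at 12 weeks (n = 3 each, difference −1.53, SE 0.16, adjusted p = 0.00063), lower in 3 of 3 arrays. It is the 1 gene called (probe ILMN_2427705), with 1508 features at an unadjusted p under 0.05. Its 12-week level is at background (percentile 18.2), so the fall's size is uncertain. The other Ak7 probe was at background in all Treg (4.37 to 4.93). Cell cycle genes were lower at 12 weeks in 29 of 32 (median −0.23, adjusted p = 9.89e-05, but 0.930 with an estimated correlation), with Bub1b of the spindle checkpoint (−1.01), Mcm2 (−0.62) and Mcm7 (−0.42) of the replication helicase and Ube2c (−0.59). Heat shock genes were lower in 14 of 17 (−0.24, adjusted p = 0.0254, but 0.930 with an estimated correlation), with Dnaja1 (−1.12), Hspd1 (−0.43), Hsph1 (−0.40) and Hspe1 (−0.24). No member of either list was called over all genes or adjusted over the list alone, and 6 cell cycle genes, all lower, had an unadjusted p under 0.05.

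The cell cycle call in NOD-LIRKO Treg was lost without replicate 3 of either age (adjusted p = 0.0937 at 8 weeks and 0.255 at 12 weeks, range over 41 alternatives 7.39e-08 to 0.930). The heat shock call was lost in 12 of 41 (2.41e-06 to 0.930), including without 8-week replicate 1 (0.104) or 3 (0.342) and without 12-week replicate 2 (0.244) or 3 (0.401). Ak7 was kept in 36 of 38 (7.67e-05 to 0.312). Not called were Lilrb4a, an inhibitory receptor (1.38, SE 0.28, adjusted p = 0.218), Tmem87b (1.30, SE 0.26, adjusted p = 0.218), Pts (0.64), Srsf5 (0.80) and Cyp51 (0.99, adjusted p = 0.369). Lower and not called were Clk1, a kinase of splicing factors (−0.82, SE 0.14, adjusted p = 0.138), Fbxo27 (−1.23, SE 0.21, adjusted p = 0.138), Itih5 (−1.06, adjusted p = 0.156) and Tpbg (−1.13, adjusted p = 0.218). Ifng differed by 0.52, Cd4 by 0.47, Serpinb1a by 0.45, Pdcd1 by 0.22, Ctla4 by 0.02, Gzmb by −0.02, Insr by −0.07, Cd8a by −0.14, Cd8b1 by −0.23, Il2ra by −0.44 and Foxp3 by −0.55 (SE 0.41, adjusted p = 0.889). The other 3 Foxp3 probes differed by −0.57, −1.08 (SE 0.46, adjusted p = 0.728, unadjusted p under 0.05) and −0.62. The 12-week group holds replicate 3, which is low in Treg signature genes and without which the chosen Foxp3 probe differed by 0.05. The second probes of Cd8a and Cd8b1 differed by −0.06 and 0.28. Lilrb4a and Tmem87b are at background at 8 weeks and Tpbg at 12 weeks.

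In NOD-Lox Treg, 2 lists were lower at 12 than at 8 weeks and no gene was called (limma, smallest adjusted p = 0.0729, 2009 features at an unadjusted p under 0.05). Monocyte and macrophage markers were lower in 15 of 18 (median −0.41, adjusted p = 0.00571, but 0.658 with an estimated correlation), with Vcam1 (−1.50), Mpeg1 (−0.95), Hmox1 (−0.89) and the complement gene C1qc (−0.71), none of them called adjusted over the list alone. Cholesterol and lipid synthesis genes were lower in 12 of 16 (−0.39, adjusted p = 0.0170, but 0.107 with an estimated correlation, and adjusted p = 0.00134 with fry), with Cyp51 (−1.07, adjusted p = 0.0132 over the list alone), Scd2 (−0.85), Lss (−0.81) and Sc5d (−0.54). The cholesterol list median per array was 0.20, 0.20 and 0.14 at 8 weeks and −0.21, −0.28 and −0.06 at 12 weeks. Genes near the threshold were Abca7, a lipid transporter (−1.82, SE 0.29), Slc38a2, an amino acid transporter (−1.06, SE 0.18), Myo3b (−1.29, SE 0.22) and Opn1sw (0.85, SE 0.14), each with an adjusted p = 0.0729. Next were Dok4 (1.56, SE 0.28, adjusted p = 0.0892) and Tnfrsf1a, a TNF receptor (1.84, SE 0.34, adjusted p = 0.102). Cacna2d3 (0.93), Il17rc (0.80, adjusted p = 0.104), Sdhb (−0.93, adjusted p = 0.110) and Slc25a24 (−0.77, adjusted p = 0.113) followed. Cd8a differed by 0.39, Ifng by 0.20, Cd4 by 0.08, Foxp3 by 0.02, Ctla4 and Pdcd1 by 0.01, Cd8b1 by −0.09, Il2ra by −0.10, Serpinb1a by −0.11, Gzmb by −0.25 and Insr by −0.29. The second probes of Cd8a and Cd8b1 differed by −0.15 and 0.01, and the other 3 Foxp3 probes by −0.30, −0.02 and −0.36. Il17rc is at background at 8 weeks, Myo3b at 12 weeks and Serpinb1a at both. The monocyte call was lost without 8-week replicate 1 (0.274) or 12-week replicate 2 (0.211) over a range of 0.00215 to 0.658, and the cholesterol call without the same arrays (0.0546 and 0.204) over 0.00134 to 0.204. The gene count was 5, 6 and 6 without 12-week replicates 1, 2 and 3 and 4 without 8-week replicate 3.

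In CD8+ cells of NOD-Lox mice, interferon gamma response genes were higher at 12 than at 8 weeks in 22 of 28 (n = 3 against 2, median 0.32, adjusted p = 0.0214, but 0.560 with an estimated correlation), with Gbp3 (2.30), Gbp2 (2.15), Irgm2 (1.74) and Tap1 (1.22). No member was called over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05, both higher. The call was lost without replicate 1 of the 8-week group (0.901) and without replicate 1 of the 12-week group (0.0548), over a range of 6.23e-06 to 0.910. No gene was called (limma, 1110 features at an unadjusted p under 0.05), with Atpif1 (2.93), Zfp386 (2.70), Podnl1 (2.35), Dr1 (2.20), Csnk1a1 (2.46), Hrh2 (−1.98), Dppa5a (−1.65), Adam23 (−2.76), Pard3 (−1.41) and Ddx31 (−2.72) all at an adjusted p = 0.998. Insr differed by 0.43, Ctla4 by 0.34, Foxp3 by 0.33, Il2ra by −0.06, Pdcd1 by −0.09, Cd8b1 by −0.18, Cd4 by −0.36, Cd8a by −0.42, Gzmb by −0.64, Ifng by −0.73 and Serpinb1a by −1.28. The second Cd8a and Cd8b1 probes differed by −0.47 and 0.33. At 12 weeks Hrh2, Dppa5a, Adam23, Pard3, Gzmb, Ifng and Serpinb1a are at background, and at both ages Il2ra and Pdcd1. The count was 130 without replicate 1 of the 8-week group and 8859 without replicate 2.

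In CD8+ cells of NOD-LIRKO mice no gene or list was called with age (limma, smallest adjusted p = 0.0771 for genes and 0.0715 for lists, with 2001 features and 4 lists at an unadjusted p under 0.05). Nearest were Pla2g3 (1.97, SE 0.30, adjusted p = 0.0771, arrays overlapping), Prdx4 (1.49, SE 0.25, adjusted p = 0.103), Sprtn of DNA repair (−1.04, SE 0.17, adjusted p = 0.103), Armt1 (−1.55, SE 0.27, adjusted p = 0.103) and Ubtd2 (−2.54, SE 0.46, adjusted p = 0.116). Gpx8 (1.68), Spc25 of the kinetochore (1.36), Kcnv2 (0.74), Adh7 (−0.90) and Rnf169 (−1.19) had an adjusted p = 0.168. Gzmb, called neither here nor between genotypes, differed by 1.08 (SE 0.28, adjusted p = 0.344), Cd4 by 0.89 (SE 0.35, adjusted p = 0.495), Serpinb1a by 0.61, Il2ra by 0.39 and Ifng by 0.29. Insr differed by −0.002, Foxp3 by −0.11, Cd8a by −0.19, Cd8b1 by −0.39, Ctla4 by −0.44 and Pdcd1 by −0.60. The second Cd8a probe went the other way (0.34, SE 0.20, adjusted p = 0.682), and the second Cd8b1 probe differed by −0.17. At background at 8 weeks are Pla2g3, Prdx4, Gpx8, Spc25, Kcnv2, Gzmb, Serpinb1a, Il2ra and Ifng, and at 12 weeks Sprtn, Ubtd2, Adh7 and Pdcd1. Erythroid markers were the nearest list (with Klf1, the erythroid transcription factor, at −0.86), and the cytotoxic effector list followed at an adjusted p = 0.135. Without 12-week replicate 2, a dim array, the gene count was 7, without 8-week NOD-Lox Treg replicate 2 it was 3, and without replicate 3 of either age 1.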

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

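All tests of explanations in this part were chosen only after the result was seen, except those of conventional CD4 T cells and of array brightness. Each of the first 7 results below was picked out because a test of the difference between groups of the genotype effect passed its threshold.

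In Treg, the genotype difference of the heat shock and handling stress list changed between 8 and 12 weeks (15 of 17 genes lower, median −0.47, adjusted p = 0.000544, but 0.751 with an estimated correlation). That of the cholesterol and lipid synthesis list changed as well (12 of 16 genes higher, median 0.32, adjusted p = 0.0425, but 0.191 with an estimated correlation). In CD8+ cells, the genotype difference of interferon gamma response genes (22 of 28 lower, median −0.51, adjusted p = 0.0237), oxidative phosphorylation genes (26 of 34 lower, −0.25, adjusted p = 0.0340) and hepatocyte markers (7 of 9 higher, 0.46, adjusted p = 0.0408) changed with age, but each has an adjusted p = 0.558 with an estimated correlation. At 8 weeks, the genotype difference of interferon gamma response genes differed between Treg and CD8+ cells (21 of 28 lower, −0.26, adjusted p = 0.0460, but 0.406 with an estimated correlation). At 12 weeks, that of Xpr1 differed between Treg and CD8+ cells (2.71, SE 0.37, adjusted p = 0.0179).

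One Treg array, replicate 3 of 12-week NOD-LIRKO, has lower Treg signature genes, at a median of −0.99 against the other Treg arrays (−0.09 to 0.33 for those), with 3 Foxp3 probes at 8.39, 7.0 and 5.52 against 10.40, 9.24 and 8.63 on the others. The tables argue against a dim array (raw upper quartile 127, median of others 124) and mainly CD8+ T cells (Cd8b1 −4.51 from their mean). Some CD8+ cells stay open, as this Cd8b1 probe and Klrd1, but not the CD8 list, peak on it. Conventional CD4 T cells may be the source, since Cd4 (10.02, others up to 9.62) and Cd40lg (8.35, others up to 8.17) are highest on it, but neither list of such cells is above all other Treg arrays, so this stays open. The naive and central memory list, of which 5 of 16 genes stand in another list, is at 0.114 (others −0.19 to 0.15), and the conventional CD4 list at 0.21 (others −0.27 to 0.21). No biological explanation was tested, as only this array shows the pattern.

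Replicate 1 of 8-week NOD-Lox CD8+ cells stands apart from the other CD8+ arrays, and the 3 lists called by age in CD8+ cells lose their call without it. Liver RNA may be there and stays open, as the Alb probe, at a raw 62.2 against the array median of 58.4, is only at percentile 69.7 of the array, while hepatocyte markers are higher in this group (8-week NOD-LIRKO minus NOD-Lox −0.61, not called). Myeloid RNA stays open too, as the monocyte and macrophage list (1 of its 18 genes in another list) is at −0.05, percentile 36.0 of 10000 random lists with a median of 0.02. On an array with so little signal a low probe or list excludes nothing, a limit put on both tests after their values were seen. Little labelled RNA on the array is a candidate explanation whose needed value is there, since the raw upper quartile is 1.09 times the raw median, the lowest of all 23 arrays, and no biological explanation was tested for a single array.

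Heat shock and handling stress genes were higher in 8-week NOD-LIRKO than NOD-Lox Treg (median 0.44, adjusted p = 0.000876), but the call is lost with an estimated correlation (adjusted p = 0.454) and with fry (0.282). Array brightness as the whole cause is argued against, because with the log2 raw upper quartile as a covariate the list median is 0.55 and its adjusted p = 0.00698. Handling stress before lysis may be the source and stays open, as the 13 immediate early genes had a median of 0.18 with a 95% interval of −0.23 to 0.33 (7 higher, 6 lower), against 0.55 for the other 13 list genes, 11 of them higher. A difference by genotype at this age stays open too and was not tested apart from handling, since the labels give no order of sample preparation.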

How the results depend on the processing

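The tests with the 2 dim arrays or all 3 arrays that stand apart left out, the upper 50% of probes, the probe of largest variance and the surrogate variable were chosen after the results were seen, and the other alternatives were fixed before the data were examined. No called list or named called gene turned direction in any alternative. Other called genes were not checked. The 12 lists called outside the comparison of cell types, taken over the alternatives other than leaving out 1 array, kept their call in 145 checks and lost it in 69, and with 1 array left out they kept it in 228 and lost it in 48. The 20 lists called between cell types kept their call in 291 and lost it in 8 checks, and in 450 and 10 with 1 array left out. Of these losses 16 are of monocyte and macrophage markers, 1 of oxidative phosphorylation and 1 of the naive list. The named genes stayed on their side of the threshold in 4373 checks, passed it newly in 160, no longer passed it in 12, and in 57, all of genes not called, changed sign by more than 1 SE. With 1 array left out these numbers were 6595, 115, 8 and 20. No paired analysis was possible, as the labels pair no samples. The counts as reported stand with the results. Below, Treg by age and CD8 by age are changes of the genotype difference with age, cell type at 8 or 12 weeks is its difference between cell types, and age in NOD-Lox (Lox) or NOD-LIRKO (LIRKO) cells is 12 against 8 weeks.

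Counts that moved, by alternative, follow, and the cause was not tested except where stated. Without array weights the gene counts were 672 for 8-week CD8, 21 for 12-week CD8, 171 for CD8 over both ages and 66 for CD8 by age. The remaining counts were 17 for cell type at 8 weeks, 0 for cell type at 12 weeks, 400 for age in Lox CD8 and 2077 for Treg against CD8. The lists called were 0 for cell type at 8 weeks, 1 for age in LIRKO Treg and 0 for age in Lox CD8. Without background correction the gene counts were 4 for 8-week Treg, 3 for 12-week CD8, 6 for age in Lox Treg, 2 for age in LIRKO Treg and 1 for age in LIRKO CD8. List counts were 4 for 8-week Treg. With a normexp offset of 50 the gene counts were 4 for 8-week Treg, 3 for 12-week CD8 and 1 for Treg by age. Beside these were 6 for age in Lox Treg, 3 for age in LIRKO Treg and 1 for age in LIRKO CD8. Among lists they were 4 for 8-week Treg. With median centring in place of quantile normalization the gene counts were 3 for 8-week Treg, 3 for 12-week Treg, 7 for 12-week CD8 and 2 for Treg over both ages. Further counts were 2 for Treg by age, 4 for age in Lox Treg, 23 for age in LIRKO CD8 and 1398 for Treg against CD8. As for lists, there were 8 for 8-week Treg, 1 for 12-week Treg, 15 for 8-week CD8, 2 for Treg over both ages, 9 for CD8 over both ages and 6 for Treg by age. In addition there were 11 for CD8 by age, 13 for cell type at 8 weeks, 7 for age in Lox Treg, 1 for age in LIRKO Treg, 8 for age in Lox CD8 and 8 for age in LIRKO CD8. With the authors' processed values the gene counts were 4 for 8-week Treg, 6 for 12-week CD8, 6 for Treg by age and 3 for cell type at 12 weeks. Other counts were 17 for age in Lox Treg, 4 for age in LIRKO Treg, 6 for age in LIRKO CD8 and 262 for Treg against CD8. Called lists were 1 for Treg by age.

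With no filter on dim probes the list counts were 4 for 8-week CD8, 4 for cell type at 8 weeks and 5 for age in Lox CD8. Testing all kept probes the gene counts were 1 for 8-week Treg, 1 for Treg by age and 1 for age in Lox Treg. Lists numbered 2 for 8-week Treg, 2 for 12-week CD8, 0 for CD8 by age, 2 for age in Lox CD8 and 3 for age in LIRKO CD8. With an intensity trend and robust variances the gene counts were 1 for 8-week Treg, 2 for 12-week CD8, 2 for age in LIRKO Treg and 1 for age in LIRKO CD8. Fitting each cell type alone the gene counts were 0 for 12-week Treg, 0 for 12-week CD8, 0 for Treg over both ages and 0 for age in LIRKO Treg. The lists called were 3 for 8-week Treg, 4 for age in Lox Treg, 1 for age in LIRKO Treg and 2 for age in LIRKO CD8. Fitting only the groups compared the gene counts were 0 for 12-week Treg, 0 for 12-week CD8, 0 for Treg over both ages, 0 for cell type at 12 weeks and 0 for age in LIRKO Treg. List counts were 1 for Treg by age, 0 for cell type at 8 weeks, 1 for age in LIRKO Treg and 0 for age in Lox CD8. At an adjusted p below 0.10 the gene counts were 7 for age in Lox Treg, 1 for age in LIRKO CD8 and 1467 for Treg against CD8. Among lists they were 5 for 8-week Treg, 4 for 8-week CD8, 3 for cell type at 8 weeks and 1 for age in LIRKO CD8. With camera and an estimated correlation the list counts were 0 for 8-week Treg, 0 for Treg by age, 0 for CD8 by age and 0 for cell type at 8 weeks. The remaining counts were 0 for age in Lox Treg, 0 for age in LIRKO Treg and 0 for age in Lox CD8. With fry the list counts were 1 for Treg over both ages, 1 for Treg by age, 0 for CD8 by age and 0 for cell type at 8 weeks. Beside these were 1 for age in Lox Treg, 0 for age in LIRKO Treg and 0 for age in Lox CD8. A looser threshold calls more by construction, and a fit of fewer arrays has fewer degrees of freedom for the spread.

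These alternatives were chosen after seeing the data. Without the 2 dim arrays the gene counts were 1 for 8-week Treg, 2 for 12-week Treg, 216 for 8-week CD8, 5 for 12-week CD8, 0 for Treg over both ages, 78 for CD8 over both ages and 1 for Treg by age. Further counts were 52 for CD8 by age, 103 for cell type at 8 weeks, 2 for cell type at 12 weeks, 2 for age in Lox Treg, 153 for age in Lox CD8, 5 for age in LIRKO CD8 and 2097 for Treg against CD8. As for lists, there were 2 for 8-week Treg, 0 for CD8 by age, 0 for cell type at 8 weeks, 0 for age in Lox CD8 and 1 for age in LIRKO CD8. Without the 2 dim arrays and replicate 3 of 12-week NOD-LIRKO Treg the gene counts were 1 for 8-week Treg, 187 for 8-week CD8, 3 for 12-week CD8, 0 for Treg over both ages, 66 for CD8 over both ages, 1 for Treg by age and 46 for CD8 by age. In addition there were 109 for cell type at 8 weeks, 2 for cell type at 12 weeks, 2 for age in Lox Treg, 131 for age in Lox CD8, 6 for age in LIRKO CD8 and 2093 for Treg against CD8. Called lists were 2 for 12-week CD8, 0 for CD8 by age and 0 for cell type at 8 weeks. Other counts were 0 for age in LIRKO Treg, 0 for age in Lox CD8 and 1 for age in LIRKO CD8. With the upper 50% of probes by mean level the gene counts were 0 for age in LIRKO Treg. Lists numbered 1 for Treg by age, 0 for CD8 by age, 0 for cell type at 8 weeks, 0 for age in Lox Treg and 0 for age in Lox CD8. With the probe of largest variance per gene the list counts were 3 for 8-week Treg, 1 for 12-week CD8, 1 for CD8 by age and 0 for cell type at 8 weeks. The remaining counts were 4 for age in Lox Treg, 1 for age in LIRKO Treg and 2 for age in Lox CD8. With 1 surrogate variable the list counts were 1 for Treg by age, 0 for CD8 by age, 0 for cell type at 8 weeks and 0 for age in Lox CD8. The cause was not tested.

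Leaving out each array in turn, the gene counts ran over 0 to 6 for 8-week Treg, 1 to 6 for 12-week Treg, 0 to 9804 for 8-week CD8, 1 to 4 for 12-week CD8, 0 to 4 for Treg over both ages and 0 to 6803 for CD8 over both ages. They ran over 0 to 3 for Treg by age, 0 to 7451 for CD8 by age, 0 to 8493 for cell type at 8 weeks and 0 to 3 for cell type at 12 weeks. With age and for cell type they ran over 0 to 6 for age in Lox Treg, 1 to 6 for age in LIRKO Treg, 0 to 8859 for age in Lox CD8, 0 to 7 for age in LIRKO CD8 and 590 to 8591 for Treg against CD8. The list counts ran over 1 to 4 for 8-week Treg, 0 to 1 for 12-week Treg, 0 to 0 for 8-week CD8, 0 to 2 for 12-week CD8, 0 to 1 for Treg over both ages and 0 to 0 for CD8 over both ages. Lists ran over 1 to 4 for Treg by age, 0 to 3 for CD8 by age, 0 to 2 for cell type at 8 weeks and 0 to 1 for cell type at 12 weeks, and over 0 to 5 for age in Lox Treg, 0 to 3 for age in LIRKO Treg, 0 to 1 for age in Lox CD8, 0 to 2 for age in LIRKO CD8 and 19 to 22 for Treg against CD8.

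The gene count moved by over 1.5 times, or to or from 0, when each of the following arrays was left out alone, named by age in weeks (wk), genotype, cell type and replicate. For 8-week Treg it was 1 without 8wk LIRKO Treg 1, 12wk LIRKO Treg 3, 12wk Lox CD8 1, 2 or 3 or 12wk LIRKO CD8 2, 2 without 12wk Lox Treg 1 or 2, 5 without 8wk Lox Treg 3, and 6 without 8wk LIRKO Treg 3. For Treg over both ages it was 0 without 8wk Lox Treg 1 or 2, 2 without 8wk LIRKO Treg 3, 12wk Lox Treg 2 or 3 or 12wk LIRKO Treg 1 or 3, 3 without 12wk LIRKO Treg 2, and 4 without 12wk Lox Treg 1. For Treg by age it was 1 without 8wk Lox Treg 1 or 3, 8wk LIRKO Treg 2, 12wk Lox Treg 3, 12wk LIRKO Treg 3, 12wk Lox CD8 1, 2 or 3 or 12wk LIRKO CD8 2 or 3, 2 without 8wk LIRKO Treg 1 or 3 or 12wk Lox Treg 1, and 3 without 12wk Lox Treg 2. For cell type at 8 weeks it was 105 without 8wk Lox CD8 1, and 8493 without 8wk Lox CD8 2. For cell type at 12 weeks it was 0 without 12wk Lox Treg 1 or 3, 12wk LIRKO Treg 2, 12wk Lox CD8 3 or 12wk LIRKO CD8 1, 2 without 8wk LIRKO CD8 2 or 12wk LIRKO CD8 2 or 3, and 3 without 12wk Lox CD8 2. For age in Lox Treg it was 1 without 8wk LIRKO Treg 1 or 2, 12wk LIRKO Treg 3, 12wk Lox CD8 2 or 3 or 12wk LIRKO CD8 2, 2 without 8wk LIRKO Treg 3 or 12wk Lox CD8 1, 4 without 8wk Lox Treg 3, 5 without 12wk Lox Treg 1, and 6 without 12wk Lox Treg 2 or 3. For age in LIRKO Treg it was 2 without 12wk Lox Treg 2 or 3, 3 without 8wk LIRKO Treg 3 or 12wk LIRKO Treg 1, 4 without 8wk LIRKO Treg 1, and 6 without 12wk LIRKO Treg 3. For the other contrasts the arrays are named with the results. With 1 array of 8-week Lox CD8 left, its spread is assumed to be that of the other groups.

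The list count moved in the same way with single arrays left out. For 8-week Treg it was 2 without 8wk LIRKO Treg 2, 12wk Lox Treg 1 or 2 or 12wk Lox CD8 1, 2 or 3, and 4 without 8wk Lox Treg 3, 8wk LIRKO Treg 3 or 12wk LIRKO Treg 3. For 12-week Treg it was 1 without 12wk LIRKO Treg 1 or 2. For 12-week CD8 it was 1 without 12wk LIRKO CD8 1, and 2 without 12wk LIRKO CD8 2. For Treg over both ages it was 1 without 12wk LIRKO Treg 2. For Treg by age it was 1 without 8wk Lox Treg 1 or 2, 8wk LIRKO Treg 2, 8wk Lox CD8 2, 12wk Lox Treg 2 or 3 or 12wk Lox CD8 3, and 4 without 8wk LIRKO Treg 3. For cell type at 8 weeks it was 0 without 8wk Lox Treg 1, 2 or 3, 8wk LIRKO Treg 1, 8wk Lox CD8 1, 8wk LIRKO CD8 1 or 2, 12wk Lox Treg 1 or 3, 12wk LIRKO Treg 1 or 2 or 12wk LIRKO CD8 2, and 2 without 8wk LIRKO Treg 3. For cell type at 12 weeks it was 1 without 12wk Lox Treg 3 or 12wk LIRKO Treg 1 or 2. For age in Lox Treg it was 0 without 8wk Lox Treg 1, 1 without 12wk Lox Treg 2, 4 without 8wk LIRKO Treg 1, 2 or 3, 12wk LIRKO Treg 3, 12wk Lox CD8 1, 2 or 3 or 12wk LIRKO CD8 2, and 5 without 8wk Lox Treg 3. For age in LIRKO CD8 it was 1 without 8wk Lox Treg 1 or 12wk LIRKO CD8 1, and 2 without 8wk LIRKO CD8 1 or 12wk LIRKO CD8 2. For the other contrasts the arrays are named with the results. The cause was not tested.

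Of the called genes, Ak7 was lost with each cell type fitted alone (adjusted p = 0.246) or only the groups compared (0.312). Among the lists, heat shock in 8-week Treg and by age in Treg each kept its call in 38 of 41 alternatives, cholesterol with age in 37 of 41, cell cycle with age and monocyte markers with age in 36 of 41, and interferon gamma by age in CD8 in 33 of 41. Interferon gamma with age in NOD-Lox CD8 kept it in 31 of 41, oxidative phosphorylation in 29 of 41, heat shock with age in NOD-LIRKO Treg in 29 of 41, cholesterol by age in 28 of 41, hepatocyte markers in 20 of 40 and interferon gamma by cell type in 18 of 40. Heat shock in 8-week Treg was lost with median centring (adjusted p = 0.0533), fry (0.282) and an estimated correlation (0.454), over a range of 4.78e-05 to 0.454. With fry the 1 list called in 8-week Treg is cholesterol and lipid synthesis (adjusted p = 0.0128) in its place. With median centring the median of all features was 0.20 in 8-week CD8, −0.31 by age in CD8, −0.26 by cell type at 8 weeks, 0.13 with age in NOD-Lox CD8 and −0.14 with age in NOD-LIRKO CD8. With quantile normalization it was −0.01, 0.03, 0.02, −0.03 and 0.01 there, so list counts under centring include that shift.

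A stricter filter on detection p was not run, as the values used here hold no detection p, and the upper 50% of probes by mean level took its place. A slide block was not run, as the slide of each array is not given in the sources used here. The package sva was not used here, and limma's own surrogate variable took its place. Signal over background limits the 2 dim arrays, whose raw upper quartile is 1.09 and 1.16 times the raw median, so genes of low level cannot be told from background there.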

Other observations

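The tests of other splits of the arrays in this part were chosen after the results were seen, and the correlations between genotype differences before. Xist, transcribed from the inactive X chromosome, was at a mean of 9.73 in Treg and 9.53 in CD8+ arrays, and the sex of the mice is not given in the sources used here. The probe of Alb, the main secreted protein of hepatocytes, was at 4.51 in Treg and 4.57 in CD8+ cells, below the filter. Replicate 3 of 12-week NOD-LIRKO Treg also had the highest Klrd1 (7.46, others up to 6.67) and Cd8b1 (5.85, others up to 5.60) of the Treg arrays, while its CD8 identity list was at 0.19 (others −0.33 to 0.31).

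A hypothesis was a genotype difference shared by both ages or both cell types. It was not seen over all genes, but sharing by few, such as Dok4 over both ages in Treg, stays open. Across genes, the correlation of the differences at 8 and 12 weeks was 0.00142 in Treg, where 93 of 100 relabellings of the arrays were as large, and −0.0703 in CD8+ cells, where 69 were. The correlation between Treg and CD8+ cells at 12 weeks was −0.00280, where 85 were. The 95th percentiles of the size of r over the relabellings were 0.0361, 0.146 and 0.0516.

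Other splits of the same arrays tell what chance can give, where the real split calls something. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In 8-week Treg 2 of them gave as many lists as the real 1 (highest other 1). In 12-week Treg 5 gave as many genes as the real 1 (highest other 4), and in 12-week CD8+ cells 3 did (real 1, highest other 1). With age, 4 gave as many lists as the real 2 (highest other 2) in NOD-Lox Treg, and in NOD-LIRKO Treg 6 gave as many genes as the real 1 (highest other 15) and 7 as many lists as the real 2 (highest other 8). In NOD-LIRKO Treg the highest of the other splits calls 15 genes, several times the real 1, which would point to a structure of these samples other than age. No test of such a structure was made, and it stays open beside chance.

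Where 100 splits were drawn, chance cannot be excluded for 3 genotype results. In Treg over both ages 32 splits gave as many genes as the real 1 (highest other 4). By age in Treg, 45 gave as many lists as the real 2 (highest other 8). By cell type at 12 weeks, 11 gave as many genes as the real 1 (highest other 3).

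A real count of 0 is reached by every split, so the number of splits says nothing there and only the highest other count is of use. Of 10 splits, all 10 reached it for genes in 8-week Treg (highest other 3), lists in 12-week Treg (6) and in 12-week CD8+ cells (1), and genes with age in NOD-Lox Treg (5). So did all 10 for genes (10) and lists (2) with age in NOD-LIRKO CD8+ cells. Of 100 splits, all 100 reached it for lists in Treg over both ages (8) and genes (5) and lists (6) in CD8+ cells over both ages. So did all 100 for genes by age in Treg (4) and lists by cell type at 12 weeks (5).

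For the genes of Treg against CD8+ cells chance can be excluded, as 1 of the 100 splits, the real one, gave as many as 758 (highest other 303). For the lists 3 gave as many as 20 (highest other 21), a share under 0.05, but as other splits reach the real count chance is only made less likely.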
